A study of Drosophila melanogaster with 3 samples.

How the data were processed

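Permanganate ChIP-seq was carried out on 3 cultures of Drosophila cells, 1 library each: unheated BG3 cells, unheated S2R+ cells and S2R+ cells held at 37 °C for 15 min. Per the labels' protocols, cells grown at 24 °C were fixed with 1% formaldehyde for 10 min and then exposed to 10 mM permanganate for 1 min. The chromatin was precipitated with antibody to Rpb3, and DNA was cleaved at oxidised thymines with piperidine at 90 °C for 30 min. Fragments of 150 to 250 bp were sequenced on the SOLiD platform. The labels give the heat shock treatment in the same words for every sample, and groups were taken from the sample titles.

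The deposited values were read counts, not scaled to depth, as the file headers and the whole-number values show. Each library had 2 files. Per the file headers, one gave forward and reverse counts of read 5′ ends by position, and the other gave counts at thymine positions. Every T position carried the count of the matching strand and position in the file of all reads (100% in each library and strand). The offset between both files was 2 bases for forward reads of the unheated libraries and 1 base for those of the heat shock library, and arms were listed from 4 in the unheated files and from 2L in the heat shock files. Thus the heat shock files were laid out differently from the others, and offsets were handled per library. The aligner, the genome build, read filters and the treatment of duplicate reads are not given in the sources used here.

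The design, fixed before the data were examined, called for promoter windows, gene bodies, pause indices, pause positions and gene lists where an annotation of the files' build could be used, and for 1 kb bins in the files' own coordinates otherwise. No reference genome was used here. In the gene table used, of the assembly Release 6 plus ISO1 MT, 800 genes on 2R and 564 on 3R lay beyond the highest position of the files, so its coordinates belong to another build and the bin comparisons were made. Promoter, gene body and pausing results, and the gene lists for cell types and pathways, are not analysed here. The list of heat-induced genes served only to count chromosome arms: 17 of its 18 members had a symbol in that table.

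T reads were summed over both strands in bins of 1000 bp and scaled to reads-per-million (RPM) of the T reads on 2L, 2R, 3L, 3R, 4 and X. Bins with at least 30 T reads over both libraries were compared by the ratio of scaled counts with an exact (Clopper-Pearson, conditional binomial) 95% interval. A bin counted as higher or lower at a ratio of at least 2-fold with an interval excluding 1. The depth of the libraries makes 3 reads worth 0.727 RPM in BG3, 0.457 in unheated S2R+ and 1.81 in heat-shocked S2R+. Chains of bins whose whole interval lay past 2-fold, with at most 1 other bin between, were joined into regions. The 10 regions per direction whose best bin had the interval bound farthest from 1 were named, following the fixed rule of ranking by the bound nearest 1. Whole-region ratios therefore describe regions picked for their extreme bins.

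Sites of open DNA were added after the data were examined, as a stand-in for promoter windows. They were the 3000 strongest T positions of BG3 cells at least 2000 bp apart with at least 5 T positions within 25 bp, and reads within 50 bp were compared. Intervals of mean levels came from 1000 bootstrap draws over sites.

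The bin comparison was tested on simulated data with a 4-fold change in 200 bins. For the heat shock comparison, 100% of changed bins were recovered and 1.70% of unchanged ones were called when reads were independent. Recovery was not broken down by read depth, so it is not shown for bins near the minimum number of reads. When reads were simulated as amplified copies, 28.7% of unchanged bins were called by reads and 1.91% by distinct T positions. For the cell line comparison these shares were 1.16%, 34.5% and 1.60%. Counts of single bins by reads thus hold many false calls if the stacked reads are copies, and counts by distinct positions are given beside them.

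The alternatives fixed beforehand that applied to bins were scaling by the median ratio, all reads in place of T reads, a cap of 5 reads per position and strand, no minimum beyond 1 read in each library, and a minimum of 100 reads. Distinct positions, other bin sizes, single strands and scaling to the weakest bins (the 50% with fewest T reads over all 3 libraries) were added later. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.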

Results

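Permanganate ChIP-seq of RNA polymerase II was available for 3 libraries of Drosophila melanogaster cells, 1 per group. S2R+ cells, an embryonic line with hemocyte-like properties, were sampled without heat shock and after 15 min at 37 °C, and BG3 cells, a line from the larval central nervous system, were sampled without heat shock. Permanganate oxidises thymines in unpaired DNA. A read whose 5′ end lies next to a T (a T read) was therefore taken as a sign of open DNA in chromatin bound by Rpb3, a polymerase II subunit. Part of the T reads may be background, since reads not next to a T were present in every library. The BG3 library held 8169352 reads, of which 4129219 were T reads. The S2R+ library without heat shock held 11897654 reads and 6560011 T reads, and the heat shock library held 3021312 reads and 1653877 T reads. T reads made up 50.5%, 55.1% and 54.7% of all reads in that order. Reads were stacked to different degrees: 3.50 reads lay on each T position in BG3, 9.47 in S2R+ without heat shock and 1.83 after heat shock. Levels are given as T reads scaled to each library's total of T reads, in reads-per-million (RPM). Because each group had 1 library, differences have no replicate check and no p-value is given for a condition. Intervals are 95% exact conditional intervals that cover counting error only, and stacked reads are not independent molecules, so these intervals are too narrow. Ratios of distinct T positions are therefore given for the named regions as well, singly or as a range. Position counts can saturate in strong regions and would then understate the fold, which was not tested.

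The signal was concentrated in the same parts of the genome in all 3 libraries to a moderate degree. The strongest 1% of 1 kb bins held 17.5% of T reads in BG3, 22.96% in S2R+ without heat shock and 27.1% in S2R+ after heat shock. Across 115426 bins, which are not independent replicates, Spearman's rho was 0.602 between BG3 and unheated S2R+, 0.568 between the S2R+ libraries and 0.501 between BG3 and heat-shocked S2R+. These values are not matched for depth or for stacking of reads, so their order does not rank heat shock against cell line. Reads lay next to a T more often in strong bins than in weak ones. With bins ranked in BG3, the T share of unheated S2R+ reads was 46.5% in the lowest 50% of bins and 57.7% in the top 1%. In the heat shock library these shares were 48.4% and 62.0%.

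The first comparison asked where open DNA bound by polymerase II changed in S2R+ cells after heat shock. T reads rose in the 10 regions named by rank, 8 of which lay on 3L and 3R. These regions together covered 100 kb and took 7.32% of T reads after heat shock, against 0.157% in unheated S2R+ cells and 0.179% in BG3 cells. The region on 3L from 9364001 to 9383000 rose 57.5-fold (55.2 to 59.9), from 388 to 22310 RPM. The region on 3R from 19879001 to 19884000 rose 88.9-fold (84.97 to 93.1), from 297 to 26445 RPM. Reads not next to a T also rose, by 40.9-fold (38.8 to 43.1) in this 3L region and 77.8-fold (73.3 to 82.7) in this 3R region. The rise was thus not confined to T reads, though in each of the 10 regions the ratio of T reads was the higher one. Positions are in the files' own coordinates; the genome build is not given in the sources used here, so no gene is named for a region.

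**Figure D1:**
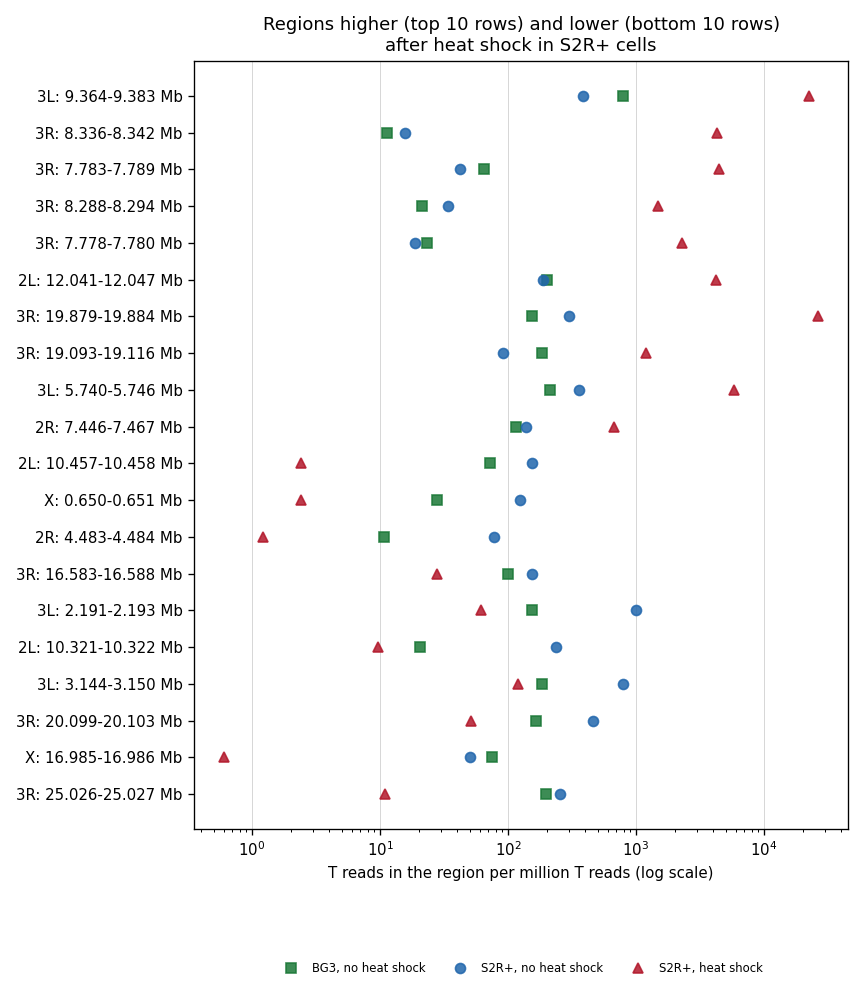
Level of T reads in RPM (log scale) in the 10 higher and the 10 lower regions of S2R+ cells after heat shock that ranked first by the interval bound of their best bin, with 1 point per library. In the upper rows the heat shock library (triangles) lies far to the right of both unheated libraries, for example 22310 against 388 and 796 RPM on 3L, and in the lower rows it lies to the left of both.

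The rise was also large in a group of regions between 7778001 and 8342000 on 3R. The region on 3R from 8336001 to 8342000 rose 271-fold (223 to 333), from 15.7 to 4256 RPM, the highest ratio among the 10. Its neighbour from 8288001 to 8294000 rose 43.4-fold (37.8 to 50.02). The regions on 3R from 7783001 to 7789000 and from 7778001 to 7780000 rose 105-fold (93.3 to 119) and 123-fold (102 to 148). On 3R from 19093001 to 19116000 the rise was 13.3-fold (12.1 to 14.6). On 3L from 5740001 to 5746000 it was 16.3-fold (15.6 to 17.1). Outside 3L and 3R, the region on 2L from 12041001 to 12047000 rose 22.4-fold (21.0 to 23.8) and the one on 2R from 7446001 to 7467000 rose 4.87-fold (4.46 to 5.33). Scaling to the weakest bins lowered these rises, for example from a log2 ratio of 5.85 to 4.63 on 3L from 9364001 and from 2.29 to 1.07 (0.95 to 1.202) on 2R from 7446001.

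All 10 regions also rose when distinct T positions were counted, by smaller ratios. These were 21.4 (15.8 to 29.9) on 3R from 8336001, 5.73 (5.18 to 6.35) on 3L from 9364001, and 2.996 (2.69 to 3.35) on 3R from 19879001, the lowest of the 10. Forward and reverse reads each rose in every one of them. On 3L from 9364001 the forward and reverse ratios were 57.5 and 57.5, while on 3R from 7783001 they were 187 and 62.8. Compared with unheated BG3 cells, the heat shock library was higher by 5.85-fold (5.25 to 6.52) on 2R from 7446001 and by 374-fold (281 to 509) on 3R from 8336001, with the other regions between these.

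Within the 3L region the T reads of unheated cells stood in narrow peaks, and those of heat-shocked cells covered broader blocks beside these peaks. In unheated S2R+ cells the strongest 100 bp window, from 9370401 to 9370500, held 23.4% of the T reads of the mapped stretch, and in BG3 the same window held 17.2%. After heat shock the strongest window, from 9370301 to 9370400, held 4.31%. It took 5 windows to hold 50% of the T reads in unheated S2R+ cells, 8 in BG3 and 18 after heat shock. The most heavily read single position held 4.28% of the region's T reads in unheated S2R+ cells and 0.293% after heat shock.

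**Figure D2:**
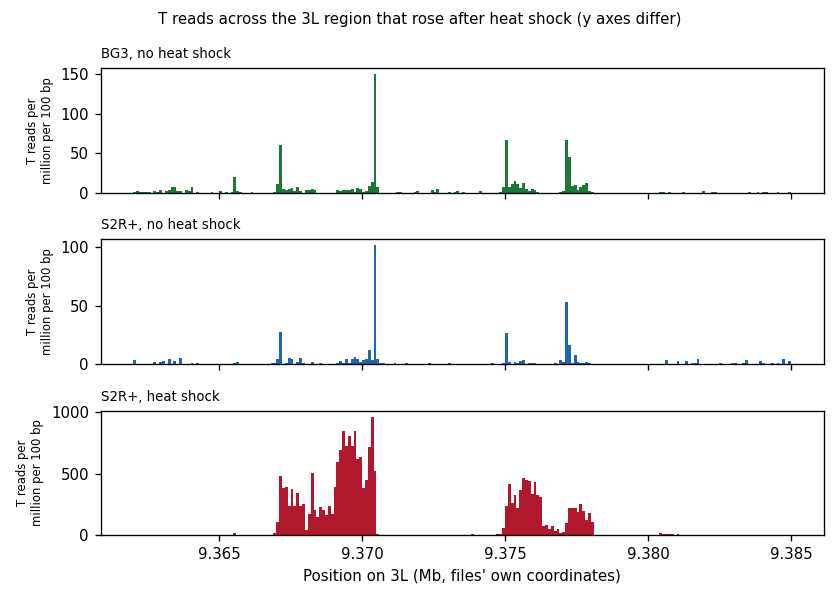
T reads in RPM per 100 bp window (y axes differ between panels) across the 3L region that rose after heat shock, by position in the files' own coordinates. The unheated libraries show a few narrow peaks of up to 149 (BG3) and 101.1 (S2R+) RPM, whereas the heat shock library reaches 962 RPM and covers whole blocks of neighbouring windows.

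Further regions gained many T reads but were not among the 10 ranked by the interval, and were chosen after their values were seen. On 3L from 3193001 to 3198000, T reads rose from 1330 to 21588 RPM, 16.2-fold (15.9 to 16.6), and 2.12-fold (1.96 to 2.30) by distinct positions. On 3R from 17121001 to 17126000 they rose 9.46-fold (9.10 to 9.83) and 3.45-fold (3.06 to 3.92) by positions. On 2R from 8052001 to 8062000 the rise was 3.65-fold (3.52 to 3.78). On X from 21834001 to 21836000, T reads went from 371 to 7636 RPM while the ratio of distinct positions was 1.05 (0.779 to 1.43), so the rise there was not seen on positions.

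Whether more bins fell or rose after heat shock depended on the settings. Of 49148 bins with at least 30 T reads over both S2R+ libraries, 14714 were at least 2-fold lower and 7548 at least 2-fold higher after heat shock, and the median log2 ratio was -0.41. This minimum counts raw reads, and the unheated library held 6560011 T reads against 1653877. Bins high in the unheated library therefore pass it at lower RPM, which favours calls of lower bins. By distinct positions 3870 bins were lower and 1755 higher among 12694. Scaling by the median ratio gave 9796 lower and 11078 higher, and scaling to the weakest bins gave 32409 lower and 1987 higher. The balance also changed without another scaling: with no minimum beyond 1 read in each library 14557 bins were lower and 21673 higher, and in bins of 2000 bp 8093 were lower and 8167 higher. All reads in place of T reads gave 14064 lower and 18723 higher. Single bins are uncertain: the log2 ratios of forward and reverse reads correlated across bins with r = 0.348, and 7243 of the lower bins and 3247 of the higher ones also passed the rule of fold and interval on distinct positions, here with no minimum number of positions.

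The 10 lower regions that ranked first by the interval bound of their best bin were short, and in each the ratio of distinct positions was below 1 as well. On 2L from 10457001 to 10458000, T reads fell from 1007 to 4, a 63.5-fold decrease (24.7 to 233) in RPM. The region on X from 650001 to 651000 was 51.4-fold lower (20.0 to 189), and the one on 2L from 10321001 to 10322000 was 24.5-fold lower (15.1 to 43.1). On 3R, the regions from 25026001 to 25027000, from 20099001 to 20103000 and from 16583001 to 16588000 were lower by 23.3-fold (14.7 to 39.3), 8.89-fold (7.17 to 11.2) and 5.56-fold (4.14 to 7.64). On 3L from 3144001 to 3150000 the decrease was 6.63-fold (5.76 to 7.68), but 10.7-fold on forward and 2.34-fold on reverse reads, 2.63-fold (2.12 to 3.27) by positions and 1.54-fold (1.32 to 1.81) against BG3. On 3L from 2191001 to 2193000 it was 16.3-fold (13.4 to 20.1), but 62.0% of the unheated T reads there lay on 1 position and by positions the decrease was 2.22-fold (1.56 to 3.21). The remaining ones held very few heat shock reads: 2 against 511 on 2R from 4483001 to 4484000, 64.4-fold lower (17.7 to 533), and 1 against 329 on X from 16985001 to 16986000, 82.9-fold lower (14.8 to 3286). By distinct positions the decreases of the 10 regions ran from 2.22-fold on 3L from 2191001 to 28.0-fold on 2R from 4483001. Reads not next to a T fell less on 2R from 4483001, by 8.12-fold (4.95 to 14.3), and the log2 ratio there was -3.84 with all reads and -2.96 in bins of 2000 bp, against -6.01. They also fell less, for example, on 3R from 25026001, by 5.15-fold (3.65 to 7.49), and on X from 650001, by 18.7-fold (8.54 to 51.4). Their decrease was close to that of T reads on 2L from 10457001 (66.0-fold) and 3L from 2191001 (15.9-fold), and larger on 3L from 3144001 (8.34-fold). Against BG3 the heat shock library was 2.13-fold (1.24 to 3.89) lower on 2L from 10321001 and 2.54-fold (2.05 to 3.16) lower on 3L from 2191001.

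At focal sites of open DNA, unheated BG3 and S2R+ cells had similar levels of T reads beside the site and heat-shocked S2R+ cells had lower ones. The 3000 strongest T positions of BG3 cells that lay at least 2000 bp apart were taken as sites, a choice made after the data were examined. The exact base carried a T read in 68.2% of sites in unheated S2R+ cells and in 41.5% after heat shock, against 1.61% and 1.66% of bases more than 500 and up to 1000 bp away. These shares are not matched for depth: the heat shock library held fewer T reads, though more distinct T positions (902487 against 692402). Between 1 and 10 bp from the site, the level was 0.948 RPM per site per bp in BG3, 0.973 in unheated S2R+ and 0.305 after heat shock. At the exact base, for which the sites were chosen in BG3, it was 10.6, 7.25 and 1.77 RPM per site. At this larger distance the levels were 0.0227, 0.0220 and 0.0245. Of 2596 sites with at least 30 T reads within 50 bp, 2063 were at least 2-fold lower after heat shock and 63 higher, with a median log2 ratio of -2.18. The minimum on raw reads favours lower calls here as well. By distinct positions, 513 of 960 sites were lower and 7 higher, with a median of -1.07. Scaling by the sites' own median ratio, which sets that median near 0, gave 471 lower and 531 higher. Scaling to the weakest bins gave 2434 lower and 20 higher, with a median of -3.39.

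By reads, the loss was deepest at the exact base of the site and faded with distance. The log2 ratio was -2.04 (bootstrap interval over sites -2.24 to -1.86) at the exact base, -1.67 (-1.84 to -1.53) at 1 to 10 bp and 0.16 (-0.19 to 0.49) at more than 500 bp. At 26 to 50 bp it was -0.48 (-0.94 to 0.07). The site on X at 21834941 supplied 18.9% of the heat shock T reads in that range, and without it the ratio was -0.77 (-1.002 to -0.54). By distinct positions the loss at these sites was not deepest at the exact base: the log2 ratio was -1.10 there, -1.30 at 1 to 10 bp and -0.34 at more than 500 bp. Sites chosen in unheated S2R+ cells instead gave -1.57 at the exact base and -1.36 at 1 to 10 bp by positions. By reads they gave -2.84, -1.37 and, at 26 to 50 bp, -0.75 (-0.96 to -0.55). Choosing sites in a compared library can itself deepen the loss.

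**Figure D3:**
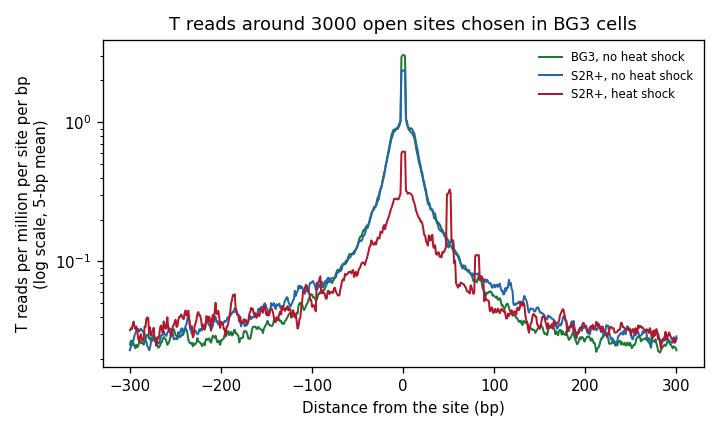
T reads in RPM per site per bp (log scale, 5 bp running mean) by distance from 3000 open sites chosen in BG3 cells, with 1 line per library. The heat shock line is lower than the unheated S2R+ line near the site, 0.305 against 0.973 at 1 to 10 bp, where the BG3 line is at 0.948. The narrow spike in the heat shock line near 50 bp lies in a range, 26 to 50 bp, where the site on X at 21834941 supplied 18.9% of T reads.

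The second comparison asked how open DNA bound by polymerase II differed between unheated BG3 and S2R+ cells. The lines differed in long blocks as well as in single bins. A 63 kb block on 2R from 1596001 to 1659000 held 546 RPM in BG3 and 8769 in S2R+, 16.05-fold lower in BG3 (15.4 to 16.7). A 53 kb block on 2R from 6948001 to 7001000 held 1651 in BG3 and 15597 in S2R+, 9.45-fold lower in BG3 (9.22 to 9.68). Reads not next to a T were lower in BG3 by 10.3-fold (9.90 to 10.7) and 9.13-fold (8.89 to 9.38) in these blocks. The 53 kb block thus differed to about the same degree in both kinds of reads, so a difference particular to open DNA is not shown there. In the other direction, 2L from 5026001 to 5040000 was 25.5-fold higher in BG3 (21.9 to 29.8), and 12.9-fold (8.48 to 20.5) by distinct positions. Reads not next to a T were 8.55-fold (7.65 to 9.59) higher there. Both 2R blocks were also prominent in heat-shocked S2R+ cells, at 10354 and 20959 RPM.

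Among the regions higher in BG3, a pair lay on chromosome 4. The region from 60001 to 87000 was 8.80-fold higher (8.11 to 9.56) and the 43 kb region from 888001 to 931000 was 6.78-fold higher (6.45 to 7.12). On 2L from 18453001 to 18480000 the ratio was 15.6 (13.9 to 17.6), and on 2R from 16831001 to 16836000 it was 206 (104 to 477), with 8 T reads in S2R+, and 33.8 (13.0 to 125) by distinct positions. On X, the regions from 1505001 to 1522000 and from 4254001 to 4276000 were 8.08-fold (7.64 to 8.54) and 6.37-fold (5.77 to 7.05) higher in BG3. On 3L from 15713001 to 15722000 the ratio was 6.11 (5.59 to 6.70). S2R+ cells had 1 T read in each of the remaining regions. On 3L from 19001 to 27000, BG3 had 813 T reads and the ratio was 1292 (231 to 51077), or 136 (24.1 to 5380) by positions. The heat shock library had 0 T reads there, where 3 would be 1.81 RPM. Reads not next to a T numbered 7 in unheated S2R+ and 0 after heat shock in this region, against 753 in BG3. Their ratio between the unheated lines was 142 (68.6 to 355), so a difference particular to open DNA is not shown there. On X from 2993001 to 2996000, BG3 had 494 T reads and the ratio was 785 (140 to 31060), or 50.5 (8.82 to 2017) by positions. The fold on X rests on 1 T read: reads not next to a T had a ratio of 13.0 (9.18 to 18.8) there, and BG3 exceeded the heat shock library by 24.7-fold (12.5 to 57.6). In the other 6 of these regions the position ratios lay between 5.67 on X from 4254001 and 10.9 on 2L from 18453001. Reads not next to a T had lower ratios than T reads on 2L from 18453001, 4.65 (4.23 to 5.12), and on 2R from 16831001, 31.6 (22.1 to 46.9). On chromosome 4 from 888001 their ratio was 7.02 (6.48 to 7.63), close to that of T reads.

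Lower regions in BG3 included a group near the end of the 2L coordinates. The decrease was 18.9-fold (13.0 to 28.6) from 22867001 to 22871000, 19.5-fold (14.6 to 26.7) from 22038001 to 22048000 and 19.4-fold (16.02 to 23.7) from 21927001 to 21941000. On 3R from 26041001 to 26044000 it was 47.9-fold (25.9 to 100.3). On 3L it was 24.9-fold (15.2 to 43.9) from 21198001 to 21202000 and 6.27-fold (5.05 to 7.86) from 14218001 to 14226000. On 2R from 6426001 to 6445000 it was 3.25-fold (3.08 to 3.42). On 3R from 6954001 to 6955000, BG3 had 1 T read against 296, 186-fold lower (33.2 to 7384), and 35.8-fold (5.75 to 1479) by positions, while reads not next to a T were 4.19-fold lower (2.30 to 8.25). By positions the other decreases ran from 3.90-fold on 2R from 6426001 to 22.8-fold on 3R from 26041001, with 13.7-fold and 6.50-fold in the long 2R blocks. In each named region of this comparison BG3 differed in the same direction from the heat shock library of S2R+ cells, but both comparisons use the single BG3 library in which the regions were picked, so this is no independent check.

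**Figure D4:**
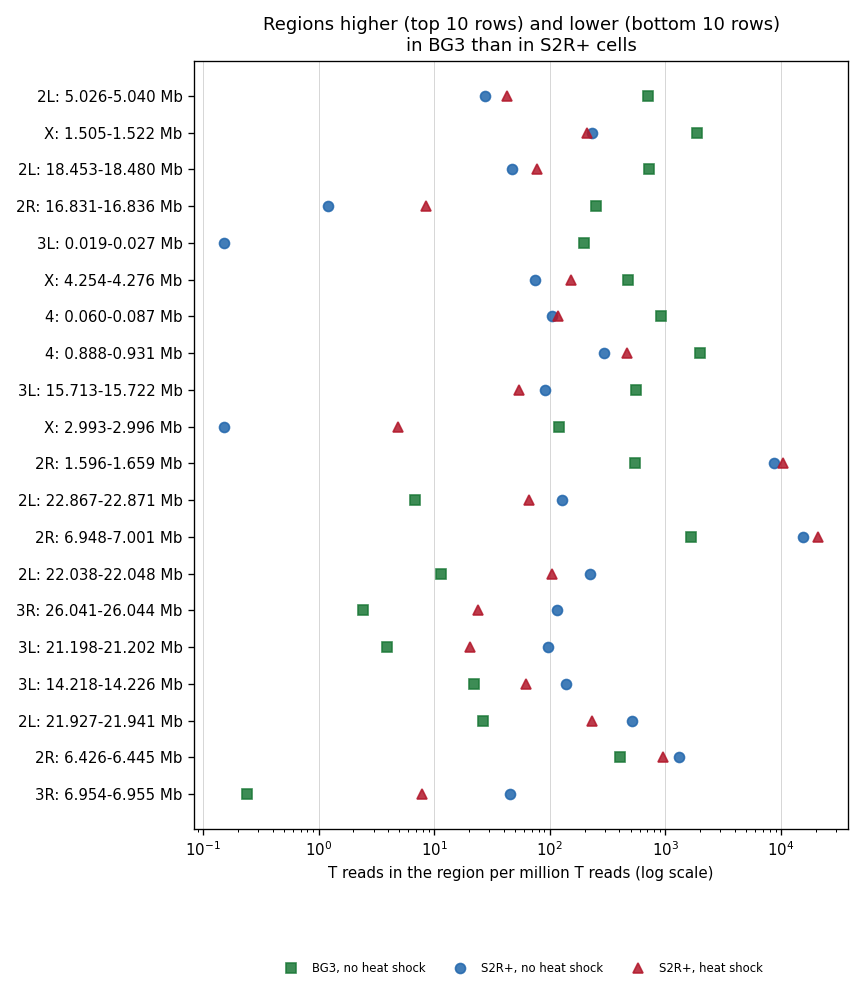
Level of T reads in RPM (log scale) in the 10 regions higher and the 10 lower in BG3 than in unheated S2R+ cells that ranked first by the interval bound of their best bin, with 1 point per library and no point where a library had 0 T reads. Both S2R+ libraries are set against the BG3 library used to pick the regions, for example at 8769 and 10354 against 546 RPM in the 2R block from 1596001.

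Across all bins, the balance of directions between the lines depended on the settings. Of 57711 bins with at least 30 T reads over both libraries, 13403 were at least 2-fold higher in BG3 and 13519 at least 2-fold lower. The minimum on raw reads lets bins high in S2R+, the deeper library, pass at lower RPM. By distinct positions, 2482 were higher and 2294 lower among 17924. Scaling to the weakest bins gave 7164 higher and 25775 lower. With no minimum beyond 1 read in each library 21510 were higher and 15933 lower, and all reads gave 26009 and 14048. Bins of 500 bp gave 16254 higher and 21215 lower, and bins of 2000 bp gave 10735 and 7595. Chromosome 4 held 1.53% of T reads in BG3, 0.862% in unheated S2R+ and 0.771% in heat-shocked S2R+, and 2R held 19.9%, 23.7% and 21.5%. Cell line and library cannot be told apart with 1 library of each.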

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

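The tests in this part were all chosen after the results were seen. Reads that do not lie next to a T were not used to call or rank regions, yet they also rose in the 10 regions that gained T reads after heat shock. In those regions the heat shock library held 41661 non-T reads-per-million of its non-T reads, against 1396 in unheated S2R+ and 1380 in BG3, a 29.8-fold difference (29.1 to 30.6) between the S2R+ libraries. The T share of reads there was 68.0% after heat shock, 58.1% in unheated S2R+ and 56.9% in BG3.

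Copies of few molecules may be considered for the rise in these 10 regions, but the ratio of distinct T positions had a lower bound of at least 2.69 in each of them, which argues against copies as the whole cause. Missing coverage in the unheated S2R+ library was considered as well. The heat shock library exceeded BG3 with a lower bound of at least 5.25 in each region. The regions were picked for bins extreme in that same heat shock library, so this is no independent check. Unheated S2R+ held 0.157% of its T reads in the 10 regions and BG3 0.179%. These near shares argue against missing coverage in the regions as a set, though BG3 is another cell line. A biological hypothesis is that the regions are heat shock gene loci, whose listed members with a symbol all lie on 3L and 3R. Of 8 regions, counting those within 100 kb of each other once, 6 lay on these arms, which hold 44.4% of tested bins (one-sided exact binomial test, p = 0.0834; p = 0.0252 with 8 of 10 regions counted singly). Neighbouring regions are not independent, so the arms do not decide, and with 1 heat shock library the treatment and the library cannot be told apart.

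The loss of T reads at open sites after heat shock was weighed against several causes. The 10 named risen regions and the 6 further regions of largest gain were left out of the totals. This shifts the log2 ratio by only 0.169 against a median loss of -2.20, which argues against reads taken up by these regions as the main cause. Reads taken up by the rest of the 1786 regions higher after heat shock, or by other weak bins, were not tested. Weaker permanganate reactivity stays open: the T share within 50 bp was 60.5% after heat shock and 63.6% without, a difference of -3.13 points (-11.0 to 1.58). By distinct positions the difference went the other way, at 5.48 points (4.77 to 6.18). Distinct positions may saturate in the deeper library, which was not tested. Uniform dilution by background also stays open: the background-subtracted log2 ratio at 1 to 10 bp minus that at 26 to 50 bp was -0.63 (-0.77 to -0.46) by reads but only -0.12 (-0.18 to -0.06) by positions. The heat shock library was laid out differently from the others and there is 1 library per group, so a separately made and processed library cannot be told apart from an effect of heat shock.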

How the results depend on the processing

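Of 58 alternatives for the 6 counts of bins and sites, 26 stayed within 1.5 times the count given in the report and 32 did not; the ratios of the 40 named regions kept their direction, a ratio past 2-fold and an interval excluding 1 in 315 of 315 alternatives, though their sizes moved. A setting that left a library at 0 reads in a region gave no ratio. The alternatives use the same libraries in which these regions were picked for extreme bins, so keeping the direction is no independent check. Alternatives by distinct positions, strand, bin size, weakest-bin scaling, a wider site window and leaving out sites near risen regions were chosen after seeing the data. Except where the construction shows it (fewer or more bins tested, or centring), the cause was not tested. For heat shock bins, the counts that moved were 9796 lower with median scaling, 18723 higher (14064 lower) with all reads, 4852 higher with the cap of 5 reads, 21673 higher (14557 lower) with no minimum, 1542 higher and 9255 lower with a minimum of 100 reads, 1987 higher and 32409 lower with scaling to the weakest bins, and 1755 higher and 3870 lower by distinct positions. Forward reads alone gave 3270 higher and reverse reads alone 3453 higher. Bins of 500 bp gave 22834 lower (6860 higher), and bins of 2000 bp gave 8093 lower (8167 higher). For BG3 against S2R+, the counts were 26009 higher (14048 lower) with all reads, 7879 lower with the cap, 21510 higher (15933 lower) with no minimum, 4175 higher and 5610 lower with a minimum of 100 reads, 7164 higher and 25775 lower with scaling to the weakest bins, and 2482 higher and 2294 lower by distinct positions. Forward reads gave 8297 higher, reverse reads 8298 higher, bins of 500 bp 21215 lower (16254 higher) and bins of 2000 bp 7595 lower (10735 higher). For open sites, distinct positions gave 7 higher and 513 lower, scaling by the sites' median 531 higher and 471 lower, and scaling to the weakest bins 20 higher (2434 lower, median log2 ratio -3.39). Promoter windows, other start sites, a background far from genes, the non-template strand, gene bodies, promoter shares, pause indices and pause positions were not run. No paired analysis was possible because each group has 1 library and the result comes from no test. Depth limits the heat shock library most, where 3 reads are 1.81 RPM.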

Other observations

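The tests in this part were all chosen after the results were seen. After heat shock, a larger share of the T reads of S2R+ cells lay in bins that were weak in BG3. With bins ranked in BG3, the lowest 50% of bins held 21.6% of T reads after heat shock and 11.7% in unheated S2R+ cells, and the top 1% held 12.1% and 16.6%. Distinct T positions moved the same way, with log2 ratios of 0.81 in the lowest 50% and -0.67 in the top 1%. Ranked in each library itself, the top 1% of bins held 14.1% of distinct positions after heat shock and 13.97% without.

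Chromosome 4, a small and largely heterochromatic chromosome, carried more T reads in BG3 than in unheated S2R+ cells, in its median bin as well as in total. The median log2 ratio was 0.82 over its 777 tested bins and -0.04 on the other arms, and that difference of 0.860 argues against a few strongly covered bins as the cause. More copies of the chromosome in BG3 cells are a candidate explanation, which would raise weak and strong bins alike. With bins ranked in the heat shock library, the excess over the other arms was 0.58 (0.19 to 1.04) in the lowest 50% of bins and 0.86 (0.55 to 1.53) in the strongest 10%, a difference of 0.281 (-0.13 to 0.89), while ranking over all 3 libraries gave 0.54 (0.11 to 1.09). Ranking over all 3 uses the compared libraries themselves, so copy number as the whole cause stays open, as does a difference between the cell lines in chromatin or transcription, which was not tested.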
